A study of Homo sapiens with 8 samples.

How the data were processed

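Total RNA from 8 samples of human ovarian cancer cells was measured by RNA-seq, and 1 table of counts per gene over 8 libraries was analysed. The deposited counts are whole numbers of reads per gene symbol, without normalisation, for 32803 symbols. Per the submitters' processing notes, the tools named were Trimmomatic 0.39, featureCounts, Subread 2.0.1 and DESeq2 1.24.0, with the human genome build GRCh37. The notes do not state the role of each tool in this series, and the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping genes, of antisense partners and of close paralogs can therefore not be told apart in these counts, and the values of histone, protocadherin and zinc finger genes are uncertain for that reason. No per-sample column was left unused.

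Each library was assigned to its group from its title, which names the BRCA1 state, resistance, passage and replicate number. The 4 groups held 2 libraries each. Nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicate libraries were compared by a chi-square test of their counts over genes, and none were alike within sampling noise. The chi-square per degree of freedom ran from 4.37 in parental proficient to 23.9 in resistant deficient libraries.

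Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. TMM factors scaled the libraries, filterByExpr kept 16221 of the 32803 genes, and all 8 libraries of the 4 groups entered 1 fit without covariates, which left 4 residual degrees of freedom. All p-values of single genes were adjusted by Benjamini-Hochberg over the genes tested. A gene rose or fell when its adjusted p was under 0.05, and counts of changed genes also required a log2 fold change of at least 1. List members given with a fold change and no p of their own passed the adjusted p. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM relative to TMM-scaled library totals, given as the mean and SD of the 2 libraries of a group. A fitted fold change against a group at 0 depends on the prior count, so a bound was computed there from a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact 95% interval from a conditional binomial test. Intervals and floors cover counting error only, since reads were not counted by molecular identifiers.

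Of the 4 comparisons, 3 are pairwise and 1 is the difference between the resistance effects of both backgrounds. The overlap of the resistance comparisons, which share no library, was tested by Fisher's exact test. The rule for named genes took BRCA1, a panel of 12 genes of PARP inhibitor response, and up to 5 genes per direction and pairwise comparison with the largest fitted fold change. The latter were protein coding, past the adjusted p, with at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups. It also took up to 3 members of each of up to 6 lists with the smallest p, moving in the direction of the list, the 5 genes per direction changed most in both resistance comparisons, and the 4 largest differences per direction. Genes named for such a difference were protein coding, past the adjusted p and at a mean of at least 5 CPM in the highest group. Some genes taken by this rule are not reported here. Gene lists were tested by limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Of 32 lists, 31 had at least 5 members among the genes tested. The list without enough members held mitochondrially encoded protein genes, of which 0 were among the genes tested. The groups, tests, lists, rule for named genes and the alternatives first listed were fixed before the data were examined.

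The alternatives first listed were RLE factors, library totals alone, no filter on low counts, a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0 with its Wald test, fits of the 2 groups alone, the replicate number as a block, each of the 8 libraries left out, and edgeR's glmTreat at a log2 fold change of 1. For lists they were an estimated correlation, other scalings, a prior count of 0.5, the block, each library left out, and limma's fry. Ranges given over the alternatives leave out the estimated correlation and fry for lists. A correction for GC content and a crossed block were added after seeing the data. The correction removed from each library its trend of log2 CPM on transcript GC content, as a natural spline with 5 degrees of freedom.

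The steps were tested on simulated data in which a seeded set of genes was changed by known amounts in each pairwise comparison. In the BRCA1-deficient resistance comparison, run on 15766 genes, 100% of the 66 genes changed 4-fold, 73.1% of the 67 changed 2-fold and 53.7% of the 67 changed 1.5-fold were recovered, and 7.69% of calls were false. For the BRCA1-proficient resistance comparison (15774 genes) the shares were 100%, 83.6% and 67.2%, with 9.62% false calls. For the parental comparison (15779 genes) they were 100%, 88.1% and 50.7%, with 6.74% false calls. A simulated GC trend in the BRCA1-deficient comparison gave 7644 calls among 15831 genes, and 2 after its removal. That trend was linear, alike in both resistant libraries and planted without any changed gene. It therefore does not show whether the correction keeps real changes or handles trends that differ between replicates. The other simulations carried no GC trend and changed far fewer genes than were called in the data.

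Names and gene neighbours were taken from the RefSeq annotation of GRCh38.p14, and transcript GC content from GENCODE transcripts of GRCh38. Since the counts were made on GRCh37, no coordinates are given. Of the 32803 symbols, 27887 matched a RefSeq symbol, 667 matched a synonym alone and 4249 had no match. GC content was known for 96.0% of the genes tested and for 100% of list members. Libraries held between 24094821 and 34394107 counts, so 3 counts over a group correspond to well under 1 CPM. With 2 libraries per group, no single library could be tested as an outlier and no other splits of the samples were counted.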

Results

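RNA-seq counts were analysed for UWB1.289, a human ovarian cancer cell line that lacks functional BRCA1, for UWB1.289+BRCA1, the same line with BRCA1 restored, and for a PARP inhibitor-resistant derivative of each. PARP inhibitors block poly(ADP-ribose) polymerases and are most toxic to cells that cannot repair DNA breaks by homologous recombination, the pathway in which BRCA1 acts. All cells were grown without drug. The 4 groups held 2 libraries each (n = 2 throughout): parental BRCA1-deficient cells at passage 29, resistant BRCA1-deficient cells at passage 56, parental BRCA1-proficient cells at passage 10 and resistant BRCA1-proficient cells at passage 45. Passage and resistance thus changed together in both backgrounds. The libraries held 29800973 and 34394107 counts (parental deficient), 27534595 and 33627021 (resistant deficient), 26125946 and 29557609 (parental proficient) and 28687819 and 24094821 (resistant proficient). The 20 most abundant genes took 7.23% to 7.74% of a library. Principal component 1 of log2 CPM held 65.1% of the variance, with all 4 BRCA1-deficient libraries on one side and all 4 BRCA1-proficient libraries on the other, and component 2 held 22.9% and separated resistant from parental libraries. Component 1 also separated the libraries by GC content. Expressed genes above 55.9% GC deviated from their mean over all libraries by a median log2 of 0.115 to 0.914 in deficient libraries. In proficient libraries this deviation was -0.577 to -0.325. BRCA1 state and GC content can therefore not be told apart on component 1.

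BRCA1 was measured first, as a check of the labels. BRCA1 mRNA stood at 35.6 ± 0.647 CPM (SD, n = 2) in parental and 34.7 ± 0.0847 CPM in resistant BRCA1-deficient cells, at 202 ± 14.4 CPM in parental BRCA1-proficient cells, and at 2271 ± 134 CPM in resistant BRCA1-proficient cells. The log2 difference between the parental lines was 2.50 ± 0.07 (SE, edgeR adjusted p = 1.16e-09), and that between resistant and parental proficient cells was 3.49 ± 0.07 (edgeR adjusted p = 1.06e-10). In deficient cells the change was -0.04 ± 0.07 (edgeR adjusted p = 0.714), which turned to 0.22 after removal of the GC trend (edgeR adjusted p = 0.00150, with 0.00150 to 0.891 over the alternatives). A count of BRCA1 mRNA does not show whether the message encodes a working protein.

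Among the panel of genes tied to PARP inhibitor response, PARP1, the main target of these drugs, fell in both resistant lines. PARP1 dropped from 638 ± 4.23 to 434 ± 12.8 CPM in deficient cells (log2 fold change -0.55 ± 0.06, edgeR adjusted p = 2.03e-05) and from 280 ± 1.81 to 141 ± 6.25 CPM in proficient cells (-0.99 ± 0.06, edgeR adjusted p = 1.98e-07). TP53BP1, which encodes the end-protection factor 53BP1, rose in proficient cells from 63.2 ± 0.217 to 118 ± 6.20 CPM (0.89 ± 0.08, edgeR adjusted p = 2.37e-06). In deficient cells its rise of 0.22 ± 0.08 (edgeR adjusted p = 0.0268, with 3.14e-06 to 0.280 over the alternatives) missed the threshold without either parental deficient library (0.148 and 0.120), without resistant deficient replicate 2 (0.280), without parental proficient replicate 1 (0.0818) and with the 2 groups alone (0.0875). ABCC1, a drug efflux transporter, rose in resistant deficient cells (0.64 ± 0.07, edgeR adjusted p = 3.31e-05) and fell in resistant proficient cells (-0.73 ± 0.07, edgeR adjusted p = 1.06e-05). CDK12, a kinase needed for transcription of long repair genes, rose in deficient cells (0.33 ± 0.06, edgeR adjusted p = 0.000846) and gave 0.07 in proficient cells (edgeR adjusted p = 0.343). RIF1, a partner of 53BP1, fell in proficient cells (-0.49 ± 0.09, edgeR adjusted p = 0.000655) and gave -0.16 in deficient cells (0.137, with 0.00408 to 0.450 over the alternatives). This last value passed as a fall without resistant deficient replicate 2 (-0.31, 0.00771) and without a filter on low counts (-0.18, 0.0266), and as a rise after removal of the GC trend (0.16, 0.00408).

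MAD2L2, a shieldin component, gave 0.66 ± 0.15 in resistant deficient cells (edgeR adjusted p = 0.00359) and 0.14 in proficient cells (0.504). The former turned to -0.29 after removal of the GC trend (0.0222, with 2.24e-05 to 0.0368 over the alternatives). SHLD2, a shieldin subunit, stayed between 32.9 and 36.1 CPM in the 4 groups and passed in no pairwise comparison (edgeR adjusted p = 0.976 in deficient, 0.695 in proficient and 0.340 between parental cells). Removal of the GC trend gave 0.31 for deficient cells (0.00167, with 0.00167 to 0.996 over the alternatives) and -0.31 between parental cells (0.00128, with 0.00128 to 0.927). SLFN11, whose product sensitises cells to replication stress, read 1.47 ± 0.0313 and 1.47 ± 0.317 CPM in parental and resistant deficient cells and 6.88 ± 0.194 and 6.78 ± 1.78 CPM in proficient cells. It differed between the parental lines (2.22 ± 0.25, edgeR adjusted p = 1.69e-05) and not with resistance (0.972 and 0.935). ABCB1, which encodes the efflux pump P-glycoprotein, was near the detection limit at 12, 16, 4 and 28 counts per group. In proficient cells its log2 fold change was 2.76 ± 1.09 (edgeR adjusted p = 0.0518), with 0.00572 to 0.223 over the alternatives, 9 of which passed. Without parental proficient replicate 2, which held all 4 parental counts, it was fitted at 6.95 (0.0460). The efflux pump gene ABCG2 stayed under 1 CPM and passed in neither resistant line (0.972 and 0.515), and PARG was listed at 0 in all 8 libraries. The annotation and counting rules are not given, so the PARG values may come from the counting and do not show absence of its mRNA.

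**Figure D1:**
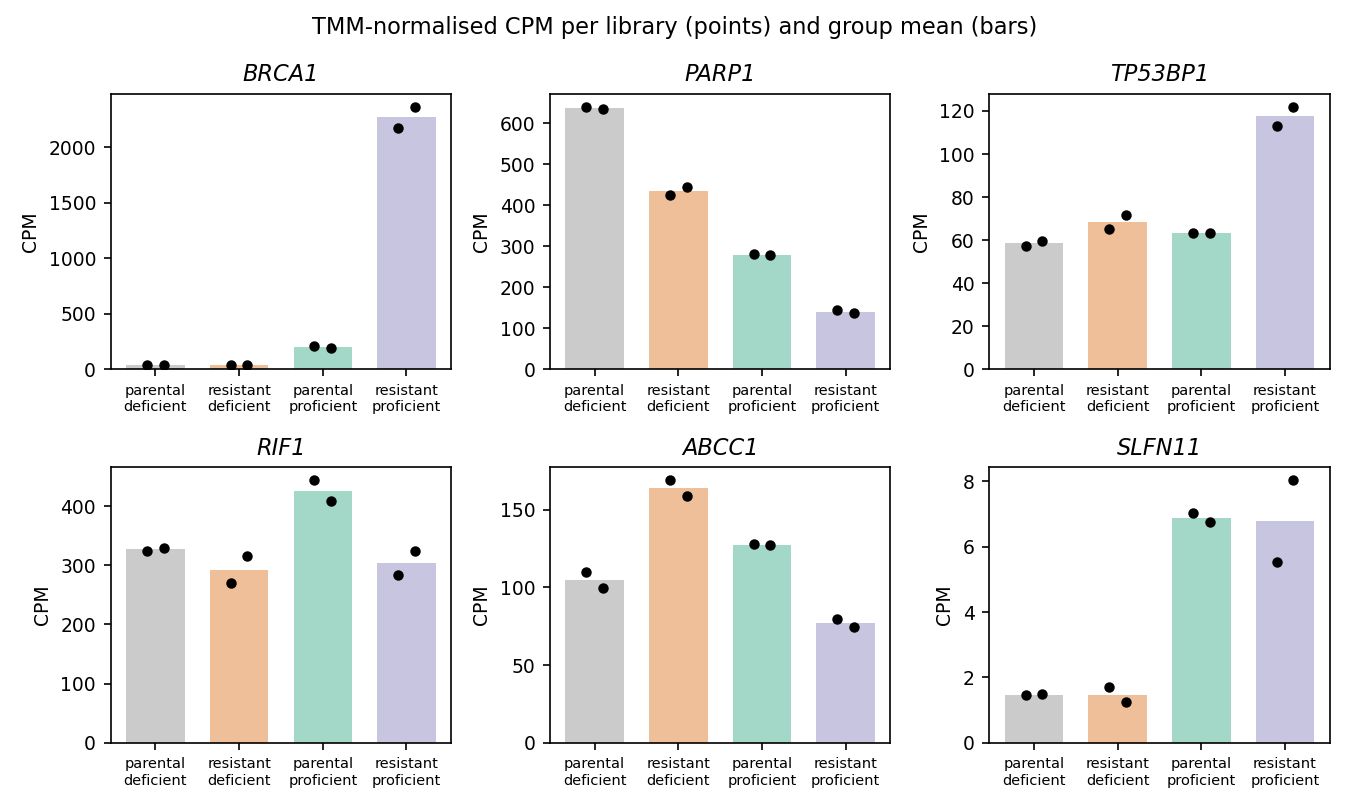
Level of BRCA1, PARP1, TP53BP1, RIF1, ABCC1 and SLFN11 in CPM on linear axes from 0, with a point for each of the 2 libraries and a bar for the mean of each of the 4 groups. BRCA1 is highest in resistant BRCA1-proficient cells (2271 CPM), and PARP1 is lower in each resistant line than in its parent.

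The comparison of resistant with parental BRCA1-deficient cells asked what distinguishes a resistant derivative that lacks BRCA1. Interferon-stimulated genes and inflammatory cytokine genes were lower in the resistant line, and ribosomal protein, histone and WNT target genes were higher. With an estimated correlation between genes, camera's call held for the interferon list (adjusted p = 0.0427) and for none of the other 4 (0.199 to 0.686). IFI44L, an interferon-induced gene, stood at 45.4 ± 0.360 CPM in parental and 1.73 ± 0.255 CPM in resistant libraries (log2 fold change -4.70 ± 0.16, edgeR adjusted p = 8.53e-09). LGR5, a WNT-responsive stem cell marker, rose from 0.544 ± 0.161 to 5.39 ± 0.0610 CPM (3.31 ± 0.30, edgeR adjusted p = 6.75e-06).

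Among the genes with the largest increases, LY6E, an interferon-inducible surface protein gene, went from 0.209 ± 0.110 to 33.5 ± 9.32 CPM (7.26 ± 0.35, edgeR adjusted p = 2.13e-07). ADAMTS10, a secreted metalloprotease gene, went from 0 counts to 5.52 ± 1.62 CPM, at least 120-fold higher. NECTIN1, a cell adhesion gene, had 2 counts in parental and 632 in resistant libraries, a ratio of 331 (95% interval 91.2 to 2737). IFT27, an intraflagellar transport gene, rose by 7.15 ± 0.52 and PPP2R2C, a phosphatase regulatory subunit gene, by 6.95 ± 0.38 on the log2 scale. In the other direction, ARMCX2 (26.2 ± 0.479 CPM in parental cells), ACSS3, PHETA2, DCAF12L1 and PNMA8A were at 0 counts in both resistant libraries and were at least 544-, 221-, 183-, 145- and 139-fold lower. The edgeR adjusted p of these 9 genes lay between 1.05e-07 (ACSS3) and 1.40e-05 (ADAMTS10).

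Of 41 interferon-stimulated genes, 34 fell, 3 rose and 4 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of -1.46 (camera adjusted p = 7.11e-11; adjusted p = 0.0427 with an estimated correlation). Besides IFI44L, the antiviral factor gene MX2 fell from 1.86 ± 0.297 CPM to 0 counts, at least 38.6-fold lower (edgeR adjusted p = 0.000332, with 2.35e-15 to 0.155 over the alternatives, the highest with DESeq2), and TRIM22 fell by 2.82 on the log2 scale (SE 0.59, edgeR adjusted p = 0.00192). The 3 that rose, named after their values were seen, were ISG15, IRF7 and IFITM2, of which IRF7 turned from 1.21 to -0.16 after removal of the GC trend. Of 23 NF-kB and inflammatory cytokine genes, 19 fell, 0 rose and 4 did not pass, also adjusted over the list alone, with a median of -0.97 (camera adjusted p = 5.09e-06; adjusted p = 0.199 with an estimated correlation). IL1B, the gene of interleukin-1 beta, changed by -4.93 ± 0.44, and the chemokine genes CXCL5 and CCL20 by -4.67 ± 0.21 and -3.28 ± 0.57.

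Of 40 cytosolic ribosomal protein genes, 29 rose, 2 fell and 9 did not pass, also adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.000215; adjusted p = 0.686 with an estimated correlation). RPLP1 rose by 1.57 ± 0.19, RPS9 by 1.33 ± 0.17 and RPS14 by 1.21 ± 0.07. Of 40 G2/M and mitosis genes, 27 fell, 2 rose and 11 did not pass, also adjusted over the list alone, with a median of -0.35, or -0.14 with the GC trend removed (camera adjusted p = 0.000215; adjusted p = 0.585 with an estimated correlation). The mitotic kinase gene CDK1 changed by -1.12 ± 0.08, and the spindle genes KIF4A and NUF2 by -1.06 ± 0.07 and -0.91 ± 0.08. Of 12 replication-dependent histone genes, 9 rose and 0 fell, and 10 rose adjusted over the list alone, with a median of 1.11 (camera adjusted p = 0.00135; adjusted p = 0.463 with an estimated correlation). H1-2 rose by 2.70 ± 0.23 and H2AC6 by 1.74 ± 0.26, while H3C10 (1.99 ± 0.49, edgeR adjusted p = 0.00498, with 0.00224 to 0.0673 over the alternatives) missed the threshold with DESeq2 (0.0653) and without parental deficient replicate 2 (0.0673). Of 22 WNT targets, 13 rose, 3 fell and 6 did not pass, also adjusted over the list alone, with a median of 0.88 (camera adjusted p = 0.00178; adjusted p = 0.585 with an estimated correlation). Besides LGR5, the receptor gene TNFRSF19 rose by 2.07 ± 0.19, and APCDD1 had 2 counts in parental and 28 in resistant libraries, a ratio of 14.7 (95% interval 3.70 to 127, edgeR adjusted p = 0.00770, with 0.00493 to 0.0737 over the alternatives), lost with DESeq2 (0.0737) and without parental deficient replicate 1 (0.0642).

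Among further lists, 21 of 33 cholesterol and fatty acid synthesis genes fell and 5 rose, also adjusted over the list alone (median -0.38, camera adjusted p = 0.00427; adjusted p = 0.199 with an estimated correlation). Of 28 genes of the integrated stress response and unfolded protein response (UPR), 15 fell and 4 rose, and 15 fell and 5 rose adjusted over the list alone (median -0.26, camera adjusted p = 0.0368; adjusted p = 0.499 with an estimated correlation). Of 24 TGF-beta targets, 15 rose and 5 fell, and 16 rose and 6 fell adjusted over the list alone (median 0.59, or 0.38 with the GC trend removed, camera adjusted p = 0.0433; adjusted p = 0.585 with an estimated correlation). The stress response call was lost with the replicate block (0.0576) and without parental deficient replicate 1 (0.0705) or resistant deficient replicate 2 (0.0813), within 0.00164 to 0.0813 over the alternatives. The TGF-beta call was lost with the block (0.0624), after removal of the GC trend (0.103) and without parental deficient replicate 1 (0.0579) or 2 (0.0550), within 0.0358 to 0.103.

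Across all genes, 1985 rose and 1197 fell at least 2-fold (edgeR), and the libraries of both groups did not overlap for 78.7% of the genes tested, against 33.3% by chance. Fold changes followed GC content (Spearman rho 0.495 across 9517 genes, which are not independent replicates), and 1245 genes rose and 1197 fell once the GC trend was removed. Without resistant deficient replicate 1, 1310 rose. Besides values given above, single values that moved by over 1.5 times included LY6E (6.20 with the GC trend removed, 7.91 without parental deficient replicate 2), IFT27 (6.07 to 11.1), TRIM22 (-3.95 to -2.12) and CCL20 (-4.42 to -2.59), the last 3 with single libraries left out.

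The comparison of resistant with parental BRCA1-proficient cells asked the same question where BRCA1 had been restored. Mitotic genes and stress response genes were lower in the resistant line, and interferon-stimulated, ribosomal protein and WNT target genes were higher. None of these 5 list calls held when camera estimated the correlation between genes (adjusted p from 0.164 to 0.570). PLK1, a kinase that drives mitosis, fell from 188 ± 3.76 to 53.3 ± 5.15 CPM (log2 fold change -1.82 ± 0.10), and SAMD9, an interferon-induced antiviral gene, rose from 4.72 ± 0.276 to 98.1 ± 12.1 CPM (4.38 ± 0.13, edgeR adjusted p = 1.37e-09). A group of neighbouring genes on chromosome 13 was reduced to between 0 and 2 counts, among them ZMYM2, a zinc finger gene of chromatin complexes.

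SALL3, a developmental transcription factor gene, went from 0 counts to 33.9 ± 3.42 CPM, at least 608-fold higher. GLB1L3, the imprinted gene PEG3, the kallikrein gene KLK5 and the collagen gene COL23A1 also went from 0 counts and were at least 260.3-, 190.4-, 169.8- and 166-fold higher. In the other direction, GJB2, which encodes the gap junction protein connexin 26, fell from 28.8 ± 0.191 CPM to 0 counts, at least 507-fold lower. ZMYM5 and the tight junction gene CLDN6 were also at 0 and at least 282- and 211-fold lower. ZMYM2 had 5931 counts in parental and 1 in resistant libraries, a ratio of 5833 (95% interval 1046 to 230416), and PSPC1, a paraspeckle gene, had 2508 and 2 counts, a ratio of 1233 (95% interval 341 to 10189). The edgeR adjusted p of these 10 genes lay between 3.21e-11 (ZMYM2) and 4.21e-07 (COL23A1).

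Of the 6 genes with at least 5 CPM in parental proficient and at most 3 counts in resistant proficient cells, 5 lay in a single stretch of chromosome 13, by the gene order of GRCh38.p14. Its 7 genes, MPHOSPH8, PSPC1, ZMYM5, ZMYM2, GJA3, GJB2 and GJB6, held 12623 counts in parental proficient and 5 counts in resistant proficient cells. In resistant BRCA1-deficient cells the same genes were expressed, with ZMYM2 at 118 ± 4.92 CPM and GJB2 at 41.5 ± 1.05 CPM. The next gene, CRYL1, kept 8.57% of its parental CPM. Beyond it IFT88 kept 95.5%, IL17D 85.4% (38 and 30 counts) and EEF1AKMT1 33.8% (319 and 105 counts). MPHOSPH8, GJA3, GJB6, CRYL1, IFT88, IL17D and EEF1AKMT1 were named after their values were seen.

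**Figure D2:**
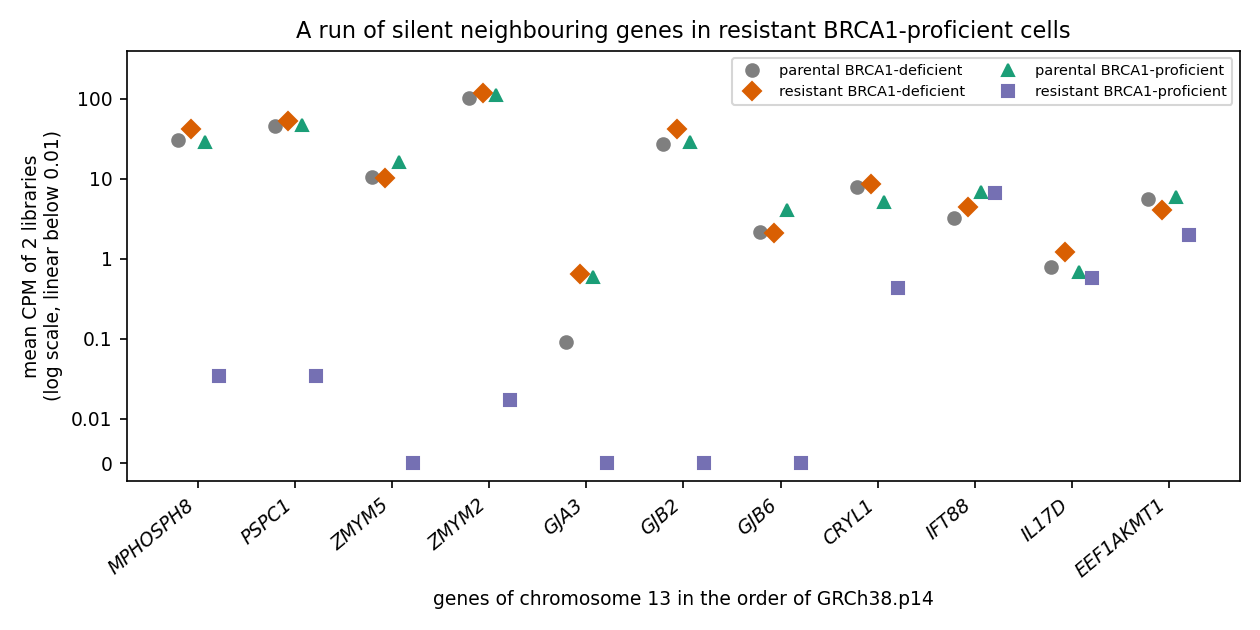
Mean level of neighbouring chromosome 13 genes in the 2 libraries of each of the 4 groups, in CPM on a log axis that is linear below 0.01, with genes evenly spaced in their order on GRCh38.p14 (distances not to scale). From MPHOSPH8 to GJB6 the resistant BRCA1-proficient cells (squares) hold 0 to 2 counts per gene, and IFT88 is at 6.62 CPM in them and 6.93 CPM in their parent (triangles).

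Of 40 G2/M and mitosis genes, 32 fell, 0 rose and 8 did not pass, and 33 fell and 1 rose adjusted over the list alone, with a median of -0.61 (camera adjusted p = 6.61e-08; adjusted p = 0.371 with an estimated correlation). Besides PLK1, HMMR changed by -1.48 ± 0.08 and the centromere histone gene CENPA by -1.42 ± 0.08. Of 28 integrated stress response and UPR genes, 21 fell, 1 rose and 6 did not pass, and 22 fell and 1 rose adjusted over the list alone, with a median of -0.81 (camera adjusted p = 8.98e-06; adjusted p = 0.169 with an estimated correlation). TRIB3 and ATF3, both induced by stress, changed by -2.68 ± 0.10 and -2.61 ± 0.11, and the UPR sensor gene ERN1 by -2.36 ± 0.15. Of 41 interferon-stimulated genes, 23 rose, 3 fell and 15 did not pass, also adjusted over the list alone, with a median of 1.46, or 0.90 with genes at their bound (camera adjusted p = 1.06e-05; adjusted p = 0.164 with an estimated correlation). TRIM22 rose by 4.16 ± 0.42 (3.50 to 5.24 with single parental proficient libraries left out) and SAMD9L by 3.79 ± 0.20.

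Of 40 cytosolic ribosomal protein genes, 26 rose, 1 fell and 13 did not pass, also adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.000908; adjusted p = 0.570 with an estimated correlation). RPL38 rose by 1.28 ± 0.08, RPL23 by 1.17 ± 0.06 and RPS27 by 1.07 ± 0.06. Of 22 WNT targets, 15 rose, 2 fell and 5 did not pass, and 16 rose and 3 fell adjusted over the list alone, with a median of 0.83 (camera adjusted p = 0.00215; adjusted p = 0.371 with an estimated correlation). The ligand gene WNT5A rose by 2.35 ± 0.12 and LGR5 by 3.02 ± 0.46. NKD2 went from 0 to 22 counts, at least 7.58-fold higher (edgeR adjusted p = 0.0417, with 0.00248 to 0.332 over the alternatives), and missed the threshold with DESeq2 (0.332) and without either parental proficient (0.120 and 0.141) or either resistant proficient library (0.0779 and 0.113). Of 43 nuclear-encoded oxidative phosphorylation genes, 23 rose, 4 fell and 16 did not pass, and 23 rose and 5 fell adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.00295; adjusted p = 0.371 with an estimated correlation). The complex I genes NDUFA2, NDUFB3 and NDUFB8 rose by 1.39 ± 0.17, 1.28 ± 0.08 and 1.03 ± 0.10.

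Among further lists, 16 of 27 replication fork protection and checkpoint genes fell and 4 rose, also adjusted over the list alone (median -0.40, camera adjusted p = 0.0158; adjusted p = 0.475 with an estimated correlation). Of 6 cancer-testis genes, 5 rose and 0 fell, also adjusted over the list alone (median 1.59, camera adjusted p = 0.0158; adjusted p = 0.371 with an estimated correlation). For NF-kB and inflammatory cytokine genes, 14 of 23 fell and 5 rose, and for histones 6 of 12 rose and 0 fell, in both lists also adjusted over the list alone (medians -0.68 and 1.13, camera adjusted p = 0.0188 for both; adjusted p = 0.371 with an estimated correlation for both). Of 24 YAP/TAZ targets, 13 fell and 5 rose, and 14 fell and 7 rose adjusted over the list alone (median -0.48, camera adjusted p = 0.0407; adjusted p = 0.371 with an estimated correlation). Of 26 PARP family and ADP-ribose removal genes, 12 fell and 3 rose, and 13 fell and 3 rose adjusted over the list alone (median -0.23, camera adjusted p = 0.0418; adjusted p = 0.371 with an estimated correlation). Of 35 homologous recombination genes, 18 fell and 4 rose, and 18 fell and 5 rose adjusted over the list alone (median -0.33, camera adjusted p = 0.0475; adjusted p = 0.475 with an estimated correlation).

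The last 3 of these calls were close to the threshold at the preset correlation, and none of them passed with an estimated one. The YAP/TAZ call was lost after removal of the GC trend (0.0569, within 0.0290 to 0.0569 over the alternatives), the PARP family call with RLE factors (0.0542), library totals (0.0621), the GC trend removed (0.0655) and without parental deficient replicate 2 (0.0519) or resistant proficient replicate 1 (0.0838), within 0.0402 to 0.0838. The homologous recombination call was lost with RLE factors (0.0548), library totals (0.0621) and without parental deficient replicate 2 (0.0519), resistant deficient replicate 1 (0.0503), parental proficient replicate 1 (0.0600) or resistant proficient replicate 1 (0.108), within 0.0393 to 0.108. Across all genes, 1684 rose and 1583 fell at least 2-fold (edgeR), without overlap of the libraries for 76.4% of genes, against 33.3% by chance.

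The comparison of the parental lines asked what differs with BRCA1 restored, at passage 10 against passage 29. Interferon-stimulated, ribosomal protein and mesenchymal genes were lower in BRCA1-proficient cells. None of these 3 list calls held with an estimated correlation (adjusted p = 0.0626, 0.471 and 0.162). OAS2, an antiviral sensor gene, stood at 118 ± 5.77 CPM in deficient and 1.35 ± 0.485 CPM in proficient cells (log2 fold change -6.43 ± 0.18). FLT1, which encodes a receptor of vascular endothelial growth factors, stood at 0.954 ± 0.233 and 73.1 ± 5.15 CPM (6.24 ± 0.17, edgeR adjusted p = 7.69e-10).

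PASD1, a cancer-testis gene, went from 0 counts to 64.7 ± 2.77 CPM, at least 1408-fold higher, and the homeobox gene NKX1-2 from 0 counts to 6.69 ± 0.911 CPM, at least 146-fold higher. TSHR, the thyrotropin receptor gene, was higher by 5.64 ± 0.33 and ADAMTSL1 by 5.63 ± 0.24 on the log2 scale. ARMCX2, the matrix metalloprotease gene MMP2, SMOC1 and the folate receptor gene FOLR2 were at 0 counts in proficient cells and at least 469-, 358-, 144- and 95.8-fold lower. NAV3 had 991 and 2 counts, a ratio of 408 (95% interval 113 to 3374). The edgeR adjusted p of these 9 genes lay between 6.00e-10 (PASD1) and 7.37e-07 (FOLR2).

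Of 41 interferon-stimulated genes, 32 fell, 5 rose and 4 did not pass, and 33 fell and 5 rose adjusted over the list alone, with a median of -2.46 (camera adjusted p = 7.07e-09; adjusted p = 0.0626 with an estimated correlation). XAF1 changed by -7.00 ± 0.35, and MX2 was at 0 in proficient cells, at least 33.2-fold lower (edgeR adjusted p = 0.000295, with 1.43e-14 to 0.155 over the alternatives, the highest with DESeq2). Of 40 cytosolic ribosomal protein genes, 34 fell, 3 rose and 3 did not pass, also adjusted over the list alone, with a median of -0.75 (camera adjusted p = 3.98e-07; adjusted p = 0.471 with an estimated correlation). RPS15 and RPLP1 changed by -2.02 ± 0.22 and -1.66 ± 0.20, and RPL35 fell from 335 ± 10.5 to 119 ± 15.4 CPM. Their share of all counts fell from 6.15% and 6.06% in the deficient to 4.02% and 4.24% in the proficient libraries, while the mitochondrial ribosomal RNA gene RNR2 went from 1.03% and 1.08% to 2.84% and 2.77%. Of 26 mesenchymal genes, 15 fell, 3 rose and 8 did not pass, also adjusted over the list alone, with a median of -1.07 (camera adjusted p = 0.000493; adjusted p = 0.162 with an estimated correlation). Besides MMP2, the collagen gene COL6A1 changed by -8.48 ± 0.43. COL6A3 went from 13 counts to 0, at least 3.72-fold lower (edgeR adjusted p = 0.0322, with 0.000851 to 0.152 over the alternatives), and missed the threshold without parental deficient replicate 1 (0.152) and without either parental proficient library (0.0948 and 0.112).

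Of 23 NF-kB and inflammatory cytokine genes, 15 fell and 2 rose, and 15 fell and 3 rose adjusted over the list alone, with a median of -0.76, or -0.32 with the GC trend removed (camera adjusted p = 0.00511; adjusted p = 0.383 with an estimated correlation). IL1B, the chemokine gene CCL2 and the signalling adaptor gene TRAF1 changed by -3.88 ± 0.40, -2.43 ± 0.24 and -2.35 ± 0.30. Of 40 G2/M and mitosis genes, 25 rose and 5 fell, and 26 rose and 5 fell adjusted over the list alone, with a median of 0.32, or 0.11 with the GC trend removed (camera adjusted p = 0.0112; adjusted p = 0.501 with an estimated correlation). CENPA, CKAP2 and NDC80 rose by 1.14 ± 0.07, 0.74 ± 0.08 and 0.74 ± 0.09, and the list's call was lost after removal of the GC trend (0.167, within 0.00892 to 0.167 over the alternatives). Of 33 cholesterol and fatty acid synthesis genes, 20 fell and 6 rose, and 21 fell and 6 rose adjusted over the list alone, with a median of -0.53, or -0.32 with the GC trend removed (camera adjusted p = 0.0199; adjusted p = 0.299 with an estimated correlation). The sterol synthesis genes LSS, NSDHL and MVD changed by -1.78 ± 0.14, -1.43 ± 0.08 and -1.42 ± 0.23.

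Among further lists, 17 of 28 integrated stress response and UPR genes rose and 7 fell, and 18 rose and 7 fell adjusted over the list alone (median 0.48, camera adjusted p = 0.0330; adjusted p = 0.383 with an estimated correlation). Of 40 G1/S and DNA replication genes, 23 fell and 8 rose, and 23 fell and 9 rose adjusted over the list alone (median -0.38, or -0.16 with the GC trend removed, camera adjusted p = 0.0351; adjusted p = 0.299 with an estimated correlation). Without parental proficient replicate 2 this call was lost (0.0502, within 0.0257 to 0.0502). Of 19 Mullerian and ovarian carcinoma markers, 11 fell and 3 rose, also adjusted over the list alone (median -0.63, or -0.48 with genes at their bound and -0.18 with the GC trend removed, camera adjusted p = 0.0351; adjusted p = 0.471 with an estimated correlation). This call was lost after removal of the GC trend (0.409) and without parental deficient replicate 1 (0.0639), parental proficient replicate 1 (0.0609), resistant deficient replicate 1 (0.0527) or 2 (0.0539), within 0.0186 to 0.409. Of the panel, PARP1 was lower in proficient parental cells (-1.19 ± 0.06, edgeR adjusted p = 4.52e-08). MAD2L2 gave -0.79 ± 0.16 (edgeR adjusted p = 0.00117) and RIF1 0.38 ± 0.09 (0.00272, or 0.0546 without parental proficient replicate 1), which turned to 0.03 (0.813) and -0.07 (0.195) after removal of the GC trend, within 7.04e-08 to 0.813 and 3.71e-06 to 0.195.

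Across all genes, 1709 were higher and 2306 lower by at least 2-fold in proficient parental cells (edgeR), without overlap of the libraries for 83.0% of genes, against 33.3% by chance. Fold changes again followed GC content (rho -0.562 across 9517 genes), and 1586 genes were higher and 1580 lower once the GC trend was removed. With it removed, RPS15, RPL35 and MVD changed by -1.35, -0.66 and -0.59, and without parental proficient replicate 2, IL1B changed by -5.05.

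**Figure D3:**
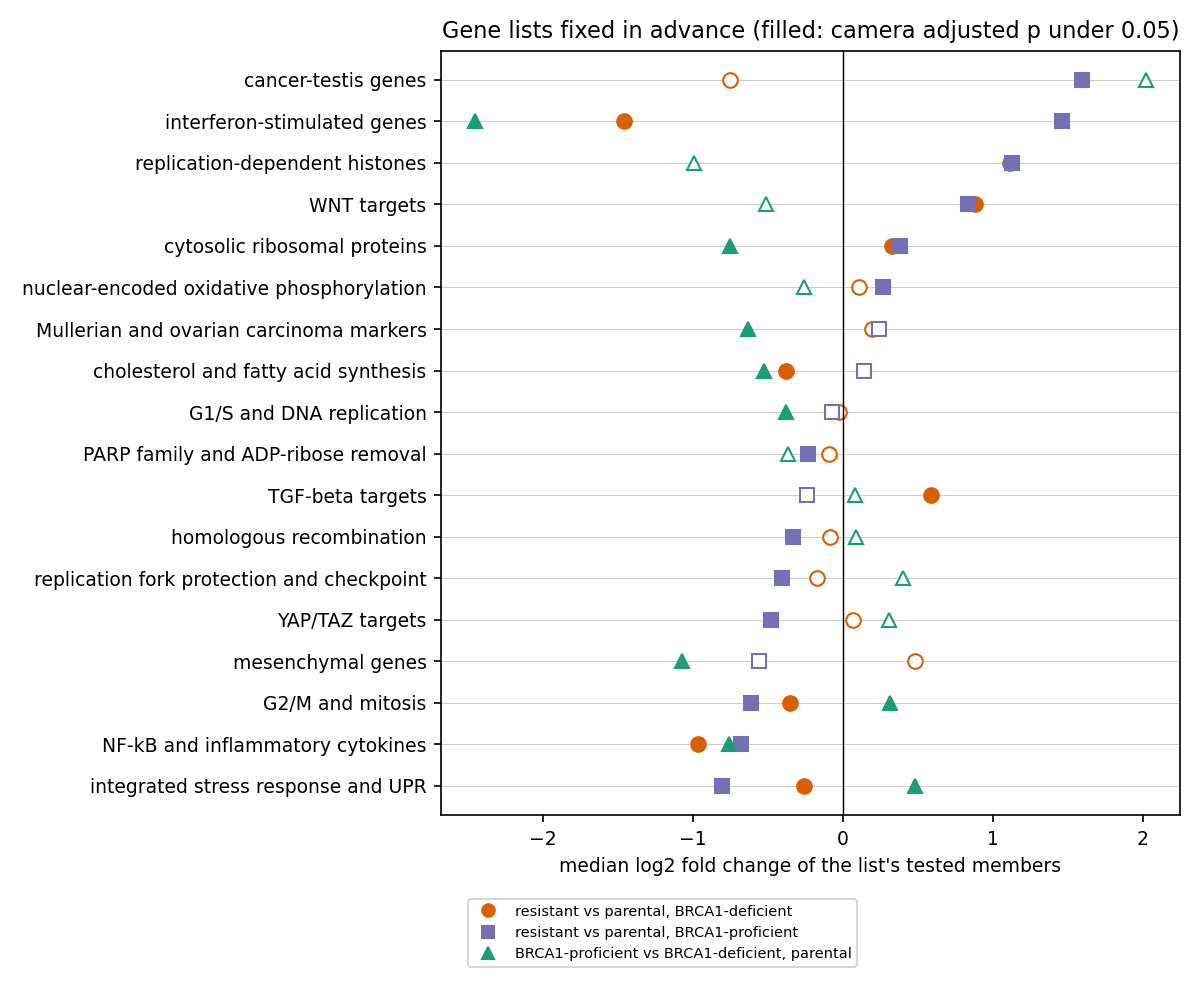
Median log2 fold change of the members of 18 gene lists in the BRCA1-deficient resistance comparison (circles), the BRCA1-proficient resistance comparison (squares) and the parental comparison (triangles), with filled symbols where camera's adjusted p at the preset correlation was under 0.05. Interferon-stimulated genes lie at -1.46, 1.46 and -2.46.

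No list of markers of other cell types passed in any pairwise comparison. Camera's adjusted p in the deficient, proficient and parental comparisons was 0.725, 0.664 and 0.236 for leukocyte markers, 0.715, 0.664 and 0.159 for fibroblast markers and 0.563, 0.856 and 0.106 for endothelial markers. The lists of 53BP1-shieldin and end joining genes (0.715, 0.906 and 0.650), Fanconi anemia genes (0.563, 0.664 and 0.834) and ABC drug transporters (0.462, 0.997 and 0.0742) did not pass either, which does not show that they were unchanged.

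Both resistant lines were then compared to ask which changes they shared. The HOX gene HOXB9, which acts in body patterning, rose in both, from 2.29 ± 0.256 to 27.2 ± 1.35 CPM in deficient cells (log2 fold change 3.57 ± 0.16) and from 0.0749 ± 0.00813 to 14.5 ± 0.757 CPM in proficient cells (7.53 ± 0.27). Parental proficient cells held very few HOXB9 counts, so the size of the latter rise is less certain than its SE. IGFN1, a gene of muscle structure, fell in both, with log2 fold changes of -3.37 ± 0.13 and -4.35 ± 0.12. TSPAN18 rose by 4.92 ± 0.32 in deficient and 4.38 ± 0.28 in proficient cells and PNMA2 by 4.50 ± 0.22 and 3.17 ± 0.22. WSCD1 went from 2.57 ± 0.0112 to 20.6 ± 4.45 CPM in deficient cells and rose by 4.60 ± 0.25 in proficient cells. HEPHL1, a copper oxidase gene, changed by -4.93 ± 0.17 and -3.97 ± 0.24. ACSS3 and DCAF12L1 were at 0 in resistant deficient cells and changed by -5.25 ± 0.28 and -6.54 ± 0.52 in proficient cells, where DCAF12L1 had 4 counts left and ranged from -10.8 to -5.40 with single libraries left out. CLDN6, at 0 in resistant proficient cells, had 369 and 2 counts in parental and resistant deficient cells, a ratio of 176 (95% interval 48.5 to 1461).

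In all, 451 genes rose and 339 fell at least 2-fold in both resistant lines, against 206.1 and 117 for independent lists. The odds ratios were 3.10 (Fisher's exact p = 4.37e-67) and 4.38 (Fisher's exact p = 1.06e-81), tests across genes, which are not independent replicates. Both comparisons followed GC content in the same direction (Spearman rho 0.495 and 0.147), and in both passage changed along with resistance. The overlap can therefore not be assigned to resistance alone. Another 105 genes rose in deficient and fell in proficient cells, against 194 for independent lists, and 153 fell in deficient and rose in proficient cells, against 124. The log2 fold changes of both comparisons, which share no library, had a Pearson r of 0.247 and a Spearman rho of 0.272 across 16221 genes. Of the lists, ribosomal protein genes, WNT targets and histones rose by camera in both comparisons, and G2/M, stress response and NF-kB genes fell in both. The summed CPM of genes picked by their histone names was 145 and 145 in parental and 181 and 158 in resistant deficient libraries. In proficient libraries it did not rise, at 178 and 179 in parental and 184 and 174 in resistant cells. None of these 12 list calls held with an estimated correlation (adjusted p from 0.169 to 0.686). That of the stress response in deficient cells was also lost with the replicate block (0.0576) and without parental deficient replicate 1 (0.0705) or resistant deficient replicate 2 (0.0813), within 0.00164 to 0.0813 over the alternatives.

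**Figure D4:**
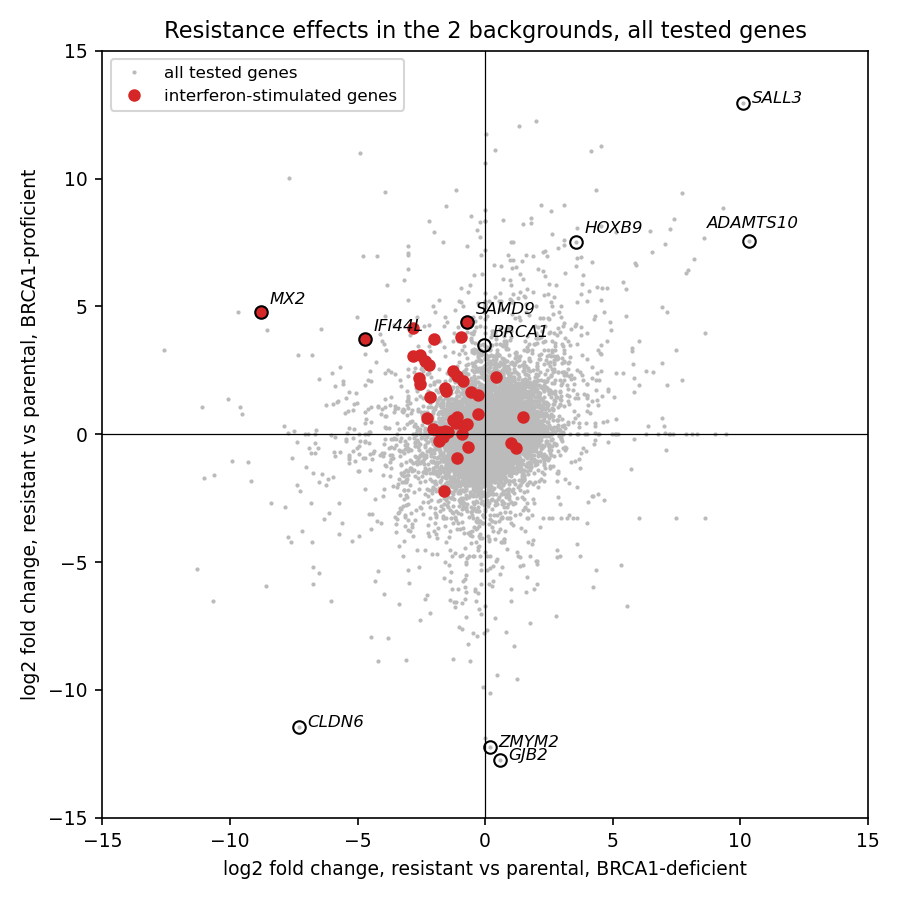
Log2 fold change of each gene tested on resistance in BRCA1-proficient cells (y axis) against that in BRCA1-deficient cells (x axis), with the 41 interferon-stimulated genes in red. BRCA1, IFI44L, SAMD9, MX2, GJB2, ZMYM2, SALL3, ADAMTS10, CLDN6 and HOXB9 are circled and named. Most red points lie at the upper left (lower in resistant deficient, higher in resistant proficient cells), and the fitted values of genes at 0 counts depend on the prior count.

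The difference between the resistance effects was tested directly, as the effect in proficient minus that in deficient cells. Interferon-stimulated genes gave the clearest difference, with a median level of 27.1 CPM in parental and 9.66 CPM in resistant deficient cells and 3.82 and 17.3 CPM in parental and resistant proficient cells. Of 41, 34 differed toward higher in proficient cells, 2 toward lower and 5 did not pass, and 34 and 3 adjusted over the list alone, with a median difference of 2.21 (camera adjusted p = 1.28e-13; adjusted p = 0.0277 with an estimated correlation). BRCA1 itself differed by 3.53 ± 0.10 (edgeR adjusted p = 1.66e-09) and ABCC1 by -1.37 ± 0.10 (edgeR adjusted p = 2.24e-06).

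Among protein-coding genes past the adjusted p and with a mean of at least 5 CPM in the highest group, the largest positive differences were in OR4C6, PCDHB8, ZNF729 and ARMCX2. OR4C6, an olfactory receptor gene, went from 0 counts to 8.80 ± 1.55 CPM in proficient cells, at least 158-fold higher, and was at 0.119 and 0 CPM in deficient cells (edgeR adjusted p of the difference = 9.53e-05). The protocadherin gene PCDHB8 went from 0.423 ± 0.0857 to 7.34 ± 0.369 CPM in proficient and from 1.60 ± 0.155 CPM to 0 in deficient cells (5.61e-07). ZNF729 rose from 3 to 405 counts in proficient cells, a ratio of 137 (95% interval 46.6 to 668), and was at 0.998 and 0.0289 CPM in deficient cells (5.41e-07). For ARMCX2 (0.00106), which had 0 and 2 counts in proficient cells, the call was lost without resistant proficient replicate 1 (an adjusted p of 0.999851, with 3.03e-09 to 0.999851 over the alternatives). Under the same limits, the largest negative differences were in GJB2 (3.58e-09), ZMYM2 (1.51e-10), ZMYM5 (1.71e-07) and the forkhead gene FOXL1 (6.79e-06). FOXL1 rose from 0.328 ± 0.185 to 15.9 ± 1.75 CPM in deficient cells and went from 0.441 ± 0.110 CPM to 0 in proficient cells, at least 7.76-fold lower.

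Of 33 cholesterol and fatty acid synthesis genes, 20 differed toward higher in proficient cells and 4 toward lower, and 22 and 4 adjusted over the list alone (median difference 0.48, camera adjusted p = 0.00133; adjusted p = 0.166 with an estimated correlation). Of 28 integrated stress response and UPR genes, 18 differed toward lower and 3 toward higher, and 18 and 4 adjusted over the list alone (-0.79, camera adjusted p = 0.0191; adjusted p = 0.366 with an estimated correlation). Of 6 cancer-testis genes, 3 differed toward higher and 0 toward lower, also adjusted over the list alone (2.20, camera adjusted p = 0.0224; adjusted p = 0.366 with an estimated correlation). Of 40 G2/M and mitosis genes, 19 differed toward lower and 4 toward higher, also adjusted over the list alone (-0.24, camera adjusted p = 0.0352; adjusted p = 0.855 with an estimated correlation). Of 27 HOX genes, 9 differed toward higher and 1 toward lower, also adjusted over the list alone (0.39, or 0.89 with the GC trend removed, camera adjusted p = 0.0493; adjusted p = 0.366 with an estimated correlation).

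Of these calls, that of cancer-testis genes was lost without resistant deficient replicate 2 (0.0787, within 0.0110 to 0.0787 over the alternatives). That of G2/M genes was lost with library totals (0.0615) and without parental deficient replicate 1 (0.0749), parental proficient replicate 1 (0.120), resistant deficient replicate 2 (0.182) or resistant proficient replicate 1 (0.133), within 0.000112 to 0.182. That of HOX genes was lost with RLE factors (0.0580), library totals (0.0615), a prior count of 0.5 (0.0582) and without the same 4 libraries (0.118, 0.120, 0.0898 and 0.133), within 0.0147 to 0.133. Across all genes, the effect in proficient cells was higher for 1637 and lower for 2044 by at least 2-fold (edgeR). With an estimated correlation, camera's calls held for interferon-stimulated genes in the deficient comparison and in this difference, and for no other list in any comparison. That setting also lowers camera's degrees of freedom, so a lost call does not show that correlation between genes undid it.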

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

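All tests of explanations in this part were chosen only after the results were seen, whereas the test of the difference between the resistance effects was set before. The genes and lists flagged below differed between the backgrounds by edgeR's test of that difference (camera's for gene lists), except where a list is said not to pass, with n = 2 libraries in each of the 4 groups. Values are the log2 effect in BRCA1-proficient minus that in BRCA1-deficient cells, and for genes near 0 counts the adjusted p alone.

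The resistance effect on interferon-stimulated genes differed between the backgrounds (camera adjusted p = 1.28e-13, and 0.0277 with an estimated correlation). The list's fall in deficient cells passed with an estimated correlation (0.0427), while its rise in proficient cells did not (0.164). IFI44L differed by 8.43, TRIM22 by 6.98, SAMD9 by 5.08 and SAMD9L by 4.75, and the adjusted p for MX2 was 0.00269. GC content was argued against as the whole cause, since the list passed at an adjusted p of 4.8e-13 after removal of the GC trend. A swap of the resistant libraries of both backgrounds was argued against by BRCA1, which was 65.4 times higher in the libraries labelled resistant BRCA1-proficient. Leukocytes in those cultures could not be decided on by their markers, whose median CPM was 0.221% of that of the interferon-stimulated genes. The markers belong to several blood lineages, so cells of a single lineage would barely move their median. The bar set for leukocytes was also the level of the interferon-stimulated genes themselves. Among the markers, PTPRC was at 6.24 ± 0.829 CPM and below its parental level of 12.8 ± 0.709 CPM, while CD14 was at 21.3 ± 0.983 CPM. Culture age cannot be told apart from resistance, because the resistant lines were sampled at least 27 passages after their parents, so this difference in interferon-stimulated genes may belong to resistance, to passage or to the selection of either line.

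The neighbouring chromosome 13 genes differed as well, with an adjusted p of 3.58e-09 for GJB2, 1.51e-10 for ZMYM2, 1.71e-07 for ZMYM5 and 1.72e-09 for PSPC1. Chance placement was argued against, counting the 30 genes tested with at least 1 CPM in parental and at most 3 counts in resistant proficient cells. Their longest run of neighbours was 4 genes (GJA3, under 1 CPM in the parent, ends it), and 0 of 10000 shuffles of gene order gave a run as long, which allows a share of up to 0.03%. GC content was argued against by a median log2 fold change of -10.1 for the stretch after removal of the GC trend, and a failure to count these genes by a median of at least 1535 counts in each of the other 3 groups. Loss of the DNA stretch could not be decided. Every gene kept at most 0.122% of its parental CPM, but the stretch was extended from MPHOSPH8 over neighbours with at most 3 counts. That low share was therefore fixed by the choice of genes. The test also asked for a set share of parental CPM in the next gene on each side. CRYL1, with 8.57%, fell below it, and the next gene on the other side, ZNF268, lies on chromosome 12. RNA counts cannot separate loss from silencing, and the chromosome 13 genes as a whole were lower in the same cells. DNA was not analysed here.

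Fold changes followed GC content most in the BRCA1-deficient and parental comparisons (Spearman rho 0.495 and -0.562). The trend was weaker in the BRCA1-proficient comparison (0.147) and in the difference (-0.290), and it bears on many of the differences below. GC-dependent library preparation or sequencing is a candidate explanation, because replicate libraries of the same group also differed along GC content, with an absolute Spearman rho across genes of at least 0.552 in each of the 4 groups. Transcript length was argued against, as its absolute rho was smaller than that of GC content in each group, with a difference of at most -0.371. A difference between groups that truly follows GC content stays open, since it would look the same in these counts.

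In all, 1637 genes differed toward higher and 2044 toward lower in proficient cells by at least 2-fold. Among the BRCA1 and drug response genes, BRCA1 differed by 3.53, TP53BP1 by 0.67, RIF1 by -0.33, CDK12 by -0.26, PARP1 by -0.44 and ABCC1 by -1.37. Inflammatory genes differed by 4.46 (IL1B) and 5.26 (CXCL5). Ribosomal protein genes differed by -1.33 (RPLP1), -1.03 (RPS9), -0.83 (RPS14), 0.69 (RPL38), 0.90 (RPL23) and 1.10 (RPS27). Mitotic genes differed by 1.02 (KIF4A), -2.19 (PLK1), -1.65 (HMMR) and -1.16 (CENPA), and stress response genes by -1.84 (TRIB3), -2.49 (ATF3) and -1.85 (ERN1). The linker histone gene H1-2 differed by 1.27, the WNT-related genes TNFRSF19 and WNT5A by -1.35 and 3.03, and the complex I genes NDUFB3 and NDUFB8 by 0.98 and 0.60. The members of lists were named for their change in single comparisons. As whole lists the inflammatory (camera adjusted p = 0.688), ribosomal protein (0.969), histone (0.724), WNT target (0.926) and oxidative phosphorylation genes (0.0986) did not pass the test of the difference.

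Of the genes that changed in the same direction in both resistant lines, HOXB9 differed in size by 3.96 (with very few counts in parental proficient cells), WSCD1 by 1.60, PNMA2 by -1.34 and IGFN1 by -0.98. PPP2R2C differed by -6.33. For genes near 0 counts in a group, the adjusted p of the difference was 0.00106 for ARMCX2 (0.999851 without resistant proficient replicate 1, within 3.03e-09 to 0.999851 over the alternatives), 0.00115 for ACSS3, 3.44e-06 for PHETA2, 4.91e-06 for PNMA8A, 0.00870 for APCDD1, 0.0110 for GLB1L3, 0.000982 for PEG3 and 1.69e-05 for KLK5. It was 9.53e-05 for OR4C6, 5.61e-07 for PCDHB8, 5.41e-07 for ZNF729 and 6.79e-06 for FOXL1. Among the lists, camera's adjusted p of the difference was 0.00133 for cholesterol and fatty acid synthesis, 0.0191 for the integrated stress response and UPR, 0.0224 for cancer-testis genes, 0.0352 for G2/M and mitosis and 0.0493 for HOX genes. With an estimated correlation none of these 5 passed (0.166, 0.366, 0.366, 0.855 and 0.366). The cancer-testis call was also lost without resistant deficient replicate 2 (0.0787, within 0.0110 to 0.0787 over the alternatives). Without parental deficient replicate 1, parental proficient replicate 1, resistant deficient replicate 2 or resistant proficient replicate 1, the G2/M call (0.0749, 0.120, 0.182 and 0.133) and the HOX call (0.118, 0.120, 0.0898 and 0.133) were lost. Both were lost with library totals (0.0615), and the HOX call also with RLE factors (0.0580) and a prior count of 0.5 (0.0582), within 0.000112 to 0.182 for G2/M and 0.0147 to 0.133 for HOX genes.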

How the results depend on the processing

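The GC-trend and crossed-block alternatives were chosen after seeing the data, the others before. Counts moved by no more than 1.5 times in 217 of 238 alternative values. Of 2284 values of named genes, 2238 kept direction and side of the threshold, 13 newly passed, 26 no longer passed and 7 reversed, and of 1860 list tests these numbers were 1714, 72, 74 and 0. With glmTreat, which by construction asks for a fold change above 2, 752 genes were higher and 577 lower in the BRCA1-deficient comparison, 799 and 789 in the BRCA1-proficient, 876 and 1039 in the parental comparison, 815 and 709 in the difference, and 144 and 136 in both resistant lines. With the GC trend removed, 1245 genes were higher in the BRCA1-deficient comparison, of which 1051 were among the 1985 before, and the median of all differences shifted by -0.11. Lists that newly passed then were epithelial genes (0.000287), oxidative phosphorylation (0.0357) and Mullerian markers (0.0491) in the deficient comparison, oxidative phosphorylation in the parental comparison (0.0113), and epithelial genes (0.0181) and Mullerian markers (0.00326) in the difference. The highest adjusted p of these 6 over the alternatives was 0.870, 0.559, 0.850, 0.213, 0.979 and 0.414. In the BRCA1-deficient comparison BRCA1 turned to 0.22, RIF1 to 0.16, SHLD2 to 0.31 and MAD2L2 to -0.29, and in the parental comparison RIF1 to -0.067, SHLD2 to -0.31 and MAD2L2 to 0.034. This alternative removes what runs along GC content, and whether that part is technical or real was not settled. Camera with an estimated correlation called 1, 0, 0 and 1 lists (deficient, proficient, parental, difference), and fry, which asks another question, 22, 23, 26 and 18. The estimated setting is stricter for its fewer degrees of freedom too. For the protocadherin genes described below, the estimated correlation was 0.00314, below the preset 0.01. Even so, camera's unadjusted p in the BRCA1-proficient comparison went from 5.79e-13 to 0.00131.

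With single libraries left out, where the lone library is assumed to vary like the other groups, the BRCA1-deficient comparison gave 1310 to 2219 higher and 1094 to 1287 lower genes and 7 to 9 lists. The BRCA1-proficient comparison gave 1538 to 1864, 1367 to 1568 and 11 to 14, the parental comparison 1445 to 1732, 1990 to 2478 and 8 to 10, and the difference 1498 to 1869, 1486 to 2102 and 3 to 9. Shared genes ranged from 362 to 482 higher and 294 to 348 lower. The lowest count of higher genes in the BRCA1-deficient comparison came without resistant deficient replicate 1. Of all libraries this one deviated most along GC content, by a log2 of 0.914 for genes above 55.9% GC, against 0.579 in replicate 2. The fewest lists in the difference came without resistant deficient replicate 2. The cause was tested in neither case.

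Replicate numbers were not shown to pair the libraries. Deviations of same-numbered libraries correlated at 0.55, 0.47 and 0.64 among 3 groups and at -0.36, -0.55 and -0.53 with parental proficient cells (9574 genes). With the replicate block, higher and lower counts were 1957 and 1193, 1681 and 1586, 1704 and 2280, 1638 and 2104, with 448 and 340 shared genes and 7, 13, 10 and 6 lists. The block ended the calls of the stress response and TGF-beta lists in the deficient comparison and added histones in the parental comparison (0.0495) and ABCB1 in proficient cells (0.0446), and changed no other call of a named gene or list. With the numbers of the parental proficient libraries crossed, counts were 1991 and 1214, 1731 and 1601, 1725 and 2347, 1669 and 2139, and 473 and 344 shared. A fit of 2 groups alone cannot give the difference. Depth limits genes with few counts, such as ABCB1, NKD2 and COL6A3.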

Other observations

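All tests in this part were chosen only after the results were seen, and camera adjusted p values here cover the 12 tests of the 3 gene classes added then. The protocadherin and zinc finger classes were chosen after runs of such genes had been seen among the increases in resistant BRCA1-proficient cells. Their p-values in that comparison and in the difference are therefore descriptive and do not test the rise independently. Clustered protocadherin genes, which encode neuronal adhesion proteins, were higher in resistant BRCA1-proficient cells. Of 40 tested protocadherin beta and gamma genes, 33 rose, 0 fell and 7 did not pass, with a median log2 fold change of 2.65 (camera adjusted p = 3.47e-12, and 0.0157 with an estimated correlation). Most had few counts, and the 8 with a mean of at least 5 CPM had a median of 1.14 with the GC trend removed, against -1.13 to 0.90 in 2000 random lists of 8 genes. PCDHB7 to PCDHB13 formed a run of 8 neighbours among the 232 genes with a log2 fold change of at least 3, at least 1 CPM and a passing edgeR adjusted p, which 0 of 10000 shuffles of 15588 ordered genes matched. Another run of 4 neighbours on chromosome 21 held PCBP3, COL6A1 and COL6A2 (9 of 10000 shuffles), and 4 runs of 3 (459 of 10000 shuffles had a run of at least 3) held ZIM2 and PEG3, ZNF99, ZNF723 and ZNF728, ZNF283 and ZNF404, and PCDHGA4, PCDHGB2 and PCDHGA5. Protocadherin genes are paralogs with overlapping transcripts, so the values of single members are uncertain. CD14, a monocyte surface gene, stood at 0.472, 0.898 and 2.47 ± 0.469 CPM in parental deficient, resistant deficient and parental proficient cells and at 21.3 ± 0.983 CPM in resistant proficient cells.

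Genes of chromosome 13 as a whole were lower in resistant BRCA1-proficient cells. Of 193 genes there with a mean of at least 5 CPM, a limit kept for all chromosome medians here, 96.9% had a log2 fold change below 0 once the GC trend was removed, with a median of -1.04, or 0.487 times the parental level, against medians from -0.20 to 0.12 in 2000 random lists of the same size. LATS2, a Hippo pathway kinase gene on this chromosome, changed by -1.08 ± 0.11 (edgeR adjusted p = 1.18e-05). In resistant BRCA1-deficient cells the chromosome 13 median was 0.01, while chromosome 5 stood at 0.48 (506 genes), chromosome 12 at -0.40 (576 genes) and chromosome 14 at -0.33 (360 genes). In the parental comparison the chromosome 5 median was 0.46.

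Whether the protocadherin genes themselves also rose in resistant BRCA1-deficient cells cannot be told apart from a shift of chromosome 5, on which they lie. Their median there was 0.502, or 0.44 with the GC trend removed, against 0.49 for 498 other chromosome 5 genes with the trend removed. Of the 40, 15 were higher, 3 lower and 22 not passed (camera adjusted p = 0.125). In proficient cells those 498 genes had a median of 0.05. The difference between the backgrounds passed (median 2.15, camera adjusted p = 6.40e-07, and 0.0276 with an estimated correlation).

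Zinc finger genes of chromosome 19 were higher in resistant BRCA1-proficient cells, where MPHOSPH8, a component of the HUSH silencing complex known to act on zinc finger genes, had 2 counts. Of 236 ZNF genes there, 138 rose, 13 fell and 85 did not pass (median 0.52, camera adjusted p = 7.65e-12, and 0.232 with an estimated correlation). For 222 ZNF genes of other chromosomes the median was 0.01 (57 rose, 63 fell, camera adjusted p = 0.881). Part of the rise may belong to chromosome 19 as a whole, since its 544 other genes had a median of 0.13 with the GC trend removed, against -0.13 to 0.05 in 2000 random lists of that size, and the 194 ZNF genes past the same limit one of 0.54. A release of this class after loss of MPHOSPH8 may account for it, but the list missed the threshold with an estimated correlation of 0.127 (p = 0.0805), which excludes nothing. In the parental comparison the same class was also higher in proficient cells (median 0.60, or 0.36 with the GC trend removed, 153 rose and 9 fell, camera adjusted p = 2.18e-09, and 0.232 with an estimated correlation), where MPHOSPH8 stood at 28.5 ± 0.879 CPM against 30.6 CPM, so a higher level of this class was also measured where MPHOSPH8 was expressed. Of other HUSH-related genes, TASOR, PPHLN1 and MORC2 fell by 0.31, 0.36 and 0.45 in resistant proficient cells, and SETDB1 did not pass (-0.04 ± 0.08, edgeR adjusted p = 0.712). In resistant deficient cells TASOR, PPHLN1 and SETDB1 fell by 0.79, 1.07 and 0.27, and MORC2 did not pass (-0.16 ± 0.07, edgeR adjusted p = 0.0956). There the class had a median of -0.15, or 0.05 with the GC trend removed (40 rose, 69 fell, camera adjusted p = 0.125).

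BRCA1 mRNA was 2271 ± 134 CPM in resistant and 202 ± 14.4 CPM in parental BRCA1-proficient cells. A copy gain of the native BRCA1 locus was argued against, since the 20 tested neighbours had a median log2 fold change of 0.104 (-1.41 to 1.03). A change of the introduced BRCA1 copy, in number or in transcription, may account for the rise and stays untested.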
